A study of Saccharomyces cerevisiae with 134 samples.

How the data were processed

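H3K36me3 ChIP-seq and RNA-seq of budding yeast (BY4741 background, grown at 30 °C) were used as processed files. All 134 samples of the study fall into 55 groups by their labels. The files used cover 36 H3K36me3 libraries and 29 RNA libraries. The remaining samples (H3 ChIP, inputs, and H3K36me3 of strains outside the 3 courses) are not analysed here.

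Per the submitters' processing notes, which give no role or order of tools, the software was bcl2fastq 2.20.0, cutadapt 1.12, STAR 2.5.2b and 2.5.4b, SAMtools 1.31 and 1.3.1, bedtools 2.26, deepTools 2.5.4, Salmon 0.8.1, R 3.3.1 and DESeq2 1.14.1. Builds named there are sacCer3 and, for fission yeast spike-in chromatin, ASM294v2. For WT and rph1Δ the deposited Salmon files give an estimated count per gene (the reads column), with TPM, length and effective length (bases). For the courses the deposited tables give TPM per gene and library with gene length. The authors' tables of changed genes give a log2 fold change with its standard error, a p-value and adjusted p-value, and a mean normalized count (another unit), and every gene listed has an adjusted p-value under 0.05. The deposited H3K36me3 tables give 1 signal value per gene and library, without a stated unit. How that signal was computed or normalized between libraries, and whether spike-in reads entered it, is not stated in the sources used here. The authors' model tables give estimates, errors and bounds of change over a course from models named ZOIBeta and ZINeg (another unit, time unit not stated).

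Estimated counts were whole numbers within 0.001 in 100% of values and were rounded. The rph1Δ against WT comparison used edgeR 4.0.16 (filterByExpr, TMM factors, quasi-likelihood test). Course tables hold TPM and no counts, although counts had been assumed when the comparisons were planned. The test for the courses was therefore chosen once the unit was known and before counts of genes under other methods were seen. It was limma 3.58.1 on log2(TPM + 1) for genes with a mean TPM of at least 1 over the libraries of the fit, with a variance trend and with time as a factor over all libraries of a course. Folds on that scale understate changes of genes near 1 TPM. Reads were also recovered from TPM with the effective lengths of the WT and rph1Δ files. These lengths are identical in those 6 files and were assumed to hold for the courses, and scaled values came out whole within 0.05 in 100% of values checked. Recovered reads served for depth, average log2 CPM and alternatives. Constant light against constant dark compared the 0 min libraries of the courses, which come from separate tables. The change of light to dark at 90 min was tested against that of dark to light at 60 min by a limma interaction.

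H3K36me3 values were analysed as log2 of the value plus 0.1 times the table median, for genes at or above the 10th percentile of mean value. Tables list 5355 genes, of which 4, 7 and 5 have missing values. Slopes per hour and the last time point against 0 min were fitted with limma, and slopes of the light to dark courses were compared by an interaction. Library medians were related to time by Spearman's rho with a permutation test of 100000 resamples (two-sided). Replicate median slopes were compared by a two-sided exact permutation test. Correlations across genes used Spearman's rho, or Pearson's r for the RNA courses.

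Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, with a threshold of 0.05. Genes outside lists were named by a rule fixed beforehand. SET2 and RPH1 were named in every RNA comparison. Among genes past the threshold with an average log2 CPM of at least 3 and no overlap between groups, the 8 largest rises and falls were named for rph1Δ, the last time points and constant light, and the 3 largest at earlier times. From each list with a member past the threshold the 2 with the smallest p were added. For slopes these were the 6 steepest and 6 shallowest past the threshold among genes at or above the median level, the 5 cryptic promoter genes, and 2 members of each list called. Dubious features, repeats and close paralogs are treated as uncertain, and since the use of strand in counting is not stated, so are overlapping genes.

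Lists of genes (23) were fixed in advance: ribosomal proteins, ribosome biogenesis, the H3K36 methylation pathway, internal cryptic promoters, genes described as repressed by Rph1, chaperones, general stress and reserve carbohydrate, oxidative stress, histones, amino acid biosynthesis, methionine and sulfur, phosphate, iron, glycolysis, respiration, alternative carbon, ergosterol, a cell, alpha cell, meiosis, G1/S, G2/M and mitochondrially encoded genes. One symbol, ARG5,6, was not found. Lists were tested with camera (preset inter-gene correlation 0.01), which compares a list with the other genes, again with camera and an estimated correlation, and with fry, which tests whether members move on balance 1 way. Gene IDs were matched to the R64 annotation for 6008 of 6692 IDs, and 684 were not matched.

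Depth per library was 9295949 to 14334963 reads for WT and rph1Δ, with 14.1% to 14.7% of reads in the top 10 genes. Recovered depth was 16022537 to 29032861 reads for dark to light and 10551857 to 27652694 for light to dark. The interval on the RPH1 rate is exact (95%) and covers counting error only. ChIP depth is not given in the files used. Within groups, correlations between libraries were at least 0.968 for RNA and 0.928 for H3K36me3, and 0 pairs were identical. Simulated data with 200 changed genes were drawn independently for each gene and library, without any shifts that real libraries share. Shares recovered from simulated data may therefore exceed those from the courses. The pipeline was tested on these data. Of changes of 2-fold it called 100% in rph1Δ, 97.0%, 95.5% and 98.5% at 20, 40 and 60 min of light, 85.1%, 94.0% and 95.5% at 30, 60 and 90 min of dark, and 91.0% in light against dark. Of 1.5-fold changes it called 55.2% to 94.0%. False calls were 2.11% to 7.54% of RNA calls. Of slope differences of 0.5 per hour between the light to dark courses it called 29.9%, and of 1 per hour 89.6%.

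Alternatives were DESeq2 1.42.0, other scaling factors, no filter, other pseudocounts, the replicate number as a block, fits of the compared time points alone, leaving out single libraries, centring H3K36me3 libraries on their medians, other correlations and other list tests. Pseudocounts of 0.1 and 5 for TPM, edgeR on recovered reads and leaving out all libraries numbered 1 were added after the data were seen. Work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.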

Results

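Budding yeast in which SET2 is deleted carried LANS-Set2, a light-activated nuclear shuttle fused to Set2, the methyltransferase that modifies lysine 36 of histone H3. Blue light moves the fusion into the nucleus and darkness lets it leave, so the switch adds or removes trimethylated H3K36 (H3K36me3) without a change of medium. Per the labels, cells were moved from dark to light and sampled at 0, 20, 40 and 60 min, or from light to dark and sampled at 0, 30, 60 and 90 min. H3K36me3 was measured by ChIP-seq in both courses, and in a light to dark course of cells that also lack RPH1, which encodes an H3K36 demethylase. Each time point of each ChIP course had 3 libraries, and the values used here are 1 signal per gene and library for 5355 genes. RNA was sequenced in both courses of the set2Δ cells with 3 libraries per time point, except 2 at dark to light 60 min, and in 3 wild-type (WT) and 3 rph1Δ libraries. Depth was 9295949 to 14334963 assigned reads in the 6 WT and rph1Δ libraries. Reads recovered from TPM came to 16022537 to 29032861 in the 11 dark to light libraries and 10551857 to 27652694 in the 12 light to dark libraries. TPM and signals are given as mean ± SD with n = 3 per group unless another n is given, log2 changes are given ± SE, and coordinates are those of the R64 genome. Labels do not say whether replicates are separate cultures, so every p-value measures the spread between these samples.

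RPH1 (YER169W, chromosome V, 523369 to 525759) was the gene removed in the rph1Δ strain, and its RNA was nearly absent there. It had 3 reads over the rph1Δ libraries against 2792 over the WT libraries, a rate of 0.0965% of WT with a 95% exact interval from 0.0199% to 0.282% for counting error only. Its TPM was 0.0139 ± 0.0127 in rph1Δ and 16.3 ± 0.938 in WT (edgeR adjusted p = 1.03e-16). SET2 (YJL168C, chromosome X, 102227 to 104428) had a TPM of 17.2 ± 0.602 in rph1Δ and 17.1 ± 0.151 in WT (edgeR adjusted p = 0.994). In the LANS-Set2 cells SET2 reads of the construct and of the gene were not separated, so they do not check the deletion. SET2 was at 133 ± 26.8 TPM at dark to light 0 min and 125 ± 15.9 TPM at 60 min (n = 2), and at 128 ± 46.1 TPM at light to dark 0 min and 130 ± 36.8 TPM at 90 min. RPH1 means lay between 18.1 and 22.3 TPM over the course groups, and neither gene passed the threshold in any course comparison by limma.

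The ChIP courses asked how fast genes gain and lose the mark. After the switch to light the median library value over genes went from 0.0243 ± 0.00184 at 0 min through 0.0461 ± 0.00437 at 20 min and 0.0809 ± 0.0152 at 40 min to 0.109 ± 0.0163 at 60 min. The mark rose in 4810 of 4816 genes tested and fell in 0 by limma's slope test, where the count at unadjusted p under 0.05 was also 4810. The median slope was 1.87 log2 units per hour, with 5% of genes below 1.34 and 5% above 2.32. With the pseudocount added, which understates folds, the median gene was 3.60-fold higher at 60 min. These sizes depend on the pseudocount: at the table median in place of 0.1 times it the median slope was 1.09 and the median log2 change at 60 min 1.06 against 1.85. At 1/100 of the table median both were larger by 0.17. After the switch to dark the medians were 0.118 ± 0.0144, 0.0798 ± 0.00459, 0.0583 ± 0.00653 and 0.0484 ± 0.00408 at 0, 30, 60 and 90 min. There the mark fell in 4793 of 4813 genes and rose in 0, with a median slope of -0.75 per hour (-0.46 with the pseudocount at the table median). The median ratio at 90 min was 0.460 with the pseudocount added, which makes the fall look smaller. Library medians followed time with Spearman's rho 0.950 in light (permutation p = 4e-05, n = 12) and -0.950 in dark (permutation p = 3e-05, n = 12). Compared directly with 0 min, 4810 genes were higher and 3 lower at 60 min of light, and 4789 were lower and 0 higher at 90 min of dark.

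**Figure D1:**
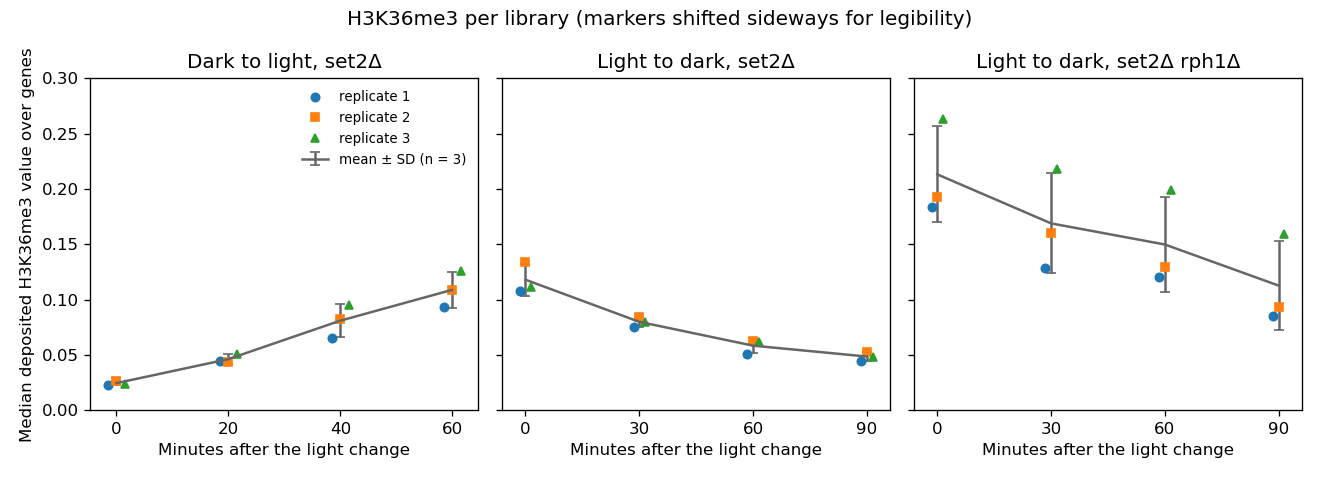
Median H3K36me3 signal over genes in each library (vertical axis, signal) against minutes after the switch (horizontal axis) in the dark to light set2Δ, light to dark set2Δ and light to dark set2Δ rph1Δ courses. Markers are libraries by replicate number, and lines join means ± SD (n = 3), which go from 0.0243 to 0.109, from 0.118 to 0.0484 and from 0.213 to 0.113.

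Genes that carry internal promoters used when H3K36 methylation is lost changed at rates close to the median gene. FLO8 (YER109C, V 375215 to 377614), an activator of filamentous growth genes, went from 0.0304 ± 0.00266 to 0.132 ± 0.0166 over 60 min of light, a slope of 1.98 ± 0.18 per hour. In the dark it went from 0.163 ± 0.0203 to 0.0738 ± 0.00698, a slope of -0.72 ± 0.08. STE11 (YLR362W, XII 849866 to 852019), a kinase of the pheromone pathway, had slopes of 2.10 ± 0.18 and -0.70 ± 0.08. The other members were SPB4, an RNA helicase of ribosome assembly, AVO1, a subunit of the TORC2 kinase, and PCA1, a cadmium exporter. Their slopes were 2.04, 1.89 and 2.00 in light and -0.79, -0.74 and -0.74 in dark, and limma adjusted p-values of these 10 slopes were at most 4.51e-09.

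Named genes with steep gain included HSP42, SSE2 and GAD1. The chaperone gene HSP42 (YDR171W, IV 806621 to 807748) rose by 2.61 ± 0.22 per hour, from 0.0374 ± 0.00772 to 0.262 ± 0.0376. SSE2, a chaperone nucleotide exchange factor, rose by 2.48 ± 0.18, and GAD1, glutamate decarboxylase, by 2.51 ± 0.17. At the other end URA1 (YKL216W, XI 25215 to 26159), a pyrimidine synthesis enzyme, rose by 1.144 ± 0.21 per hour from an already high 0.187 ± 0.0368 to 0.429 ± 0.105. The 2 short ribosomal protein genes RPL41A and RPS28B had slopes of 1.139 ± 0.17 and 1.04 ± 0.18. The 6 steepest values came from repeated or subtelomeric sequence, where reads cannot be placed with certainty: VTH1 at 4.63 and 5 features of the ASP3-3 region, which share 1 set of values, at 3.38. The other shallow ones there, YAR009C, YER138W-A and YLL066W-B, lie in or near transposon or subtelomeric sequence.

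Genes with steep loss included ILV5, RPS29A and TDH3, after 4 small, repeated or subtelomeric features that are uncertain. ILV5 (YLR355C, XII 838066 to 839253), a branched-chain amino acid enzyme, went from 0.598 ± 0.0435 to 0.154 ± 0.0200 over 90 min of dark, a slope of -1.32 ± 0.09. RPS29A went from 0.640 ± 0.0588 to 0.163 ± 0.0208 (-1.29 ± 0.08), the glycolytic gene TDH3 from 0.299 ± 0.0298 to 0.0769 ± 0.00965 (-1.25 ± 0.08), and the glycolytic gene FBA1 had a slope of -1.07 ± 0.07. CPA1, of arginine synthesis, changed by -1.72 ± 0.10 from 0 to 90 min, and the chaperone gene SSA2 fell at -1.06 ± 0.08 per hour. Shallow slopes past the threshold included the membrane proteolipid gene PMP2 (-0.47 ± 0.10), MIN10 (-0.45 ± 0.14) and RPL41A (-0.42 ± 0.13), with the dubious or subtelomeric features YCR006C, YLR112W and YLR466C-B after them. YBL111C (-2.86) and YHR214C-D (-1.96) are subtelomeric or repeated features whose steep slopes are uncertain, and the small features YMR046W-A and YCR024C-B had slopes of -1.39 and -1.33. By camera with a preset correlation 4 lists differed from the other genes in light slopes and 8 in dark slopes. With an estimated correlation 0 of the 23 lists did, the smallest adjusted p being 0.93 in light and 0.84 in dark.

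The set2Δ rph1Δ course asked whether the mark is lost more slowly without the Rph1 demethylase. ILV5 was again steep at -1.07 ± 0.15 per hour, from 0.730 ± 0.141 to 0.239 ± 0.0947, and STM1, a ribosome-binding protein gene, had -0.97 ± 0.16. FLO8 fell at -0.52 ± 0.17 and STE11 at -0.51 ± 0.18, with SPB4 at -0.60, AVO1 at -0.55 and PCA1 at -0.56. The stress sensor gene WSC4 (-0.39 ± 0.17) and RPS28B (-0.38 ± 0.15) were shallow, as were the small or dubious features YDR274C, YLR256W-A, YOR024W and YJL156W-A. COS3, YAR010C, YNL190W and YLR264C-A were steep too, the first 2 being repeated sequence. Library medians were 0.213 ± 0.0434, 0.169 ± 0.0453, 0.150 ± 0.0427 and 0.113 ± 0.0404 at 0, 30, 60 and 90 min (rho -0.691, permutation p = 0.0177, n = 12). The mark fell in 4689 of 4815 genes and rose in 0 by limma, with a median slope of -0.55 (-0.31 with the pseudocount at the table median). With the pseudocount added the median ratio was 0.549 at 90 min, where 4598 genes were lower. The count depended on which replicates were in the fit, while the size of the loss changed little. Without replicate 2 the slope test called 3 genes at a median of -0.52 and the 90 min test 0 at -0.82, and without replicate 1 the 90 min test called 12 at -0.80 (-0.86 with all). With replicate number as a block the counts were 4744 and 4758. From 0 to 90 min the library medians of replicates 1, 2 and 3 went from 0.184 to 0.0853, from 0.193 to 0.0934 and from 0.263 to 0.159, lower at each step.

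Loss was slower in the set2Δ rph1Δ course at most genes, by about the standard error of each gene. That standard error takes in level differences between replicates, as the interaction fit had no term for replicate number. The slope difference was positive, meaning slower loss without RPH1, in 4602 of 4712 genes, and its median was 0.20 per hour with quartiles of 0.15 and 0.25, beside a median SE of 0.19. Limma's interaction test called 0 genes, the smallest adjusted p being 0.547. Of the 4712 genes 119 had an unadjusted p under 0.05, all of them positive. That share is below 0.05, but 0.05 is not the share to expect here. The SE takes in level differences between replicates, and genes share the shifts of their libraries. A low share is therefore no sign that the courses are alike. Without replicate 1 the test called 26 genes and without replicate 2 it called 3. Median slopes per replicate were -0.77, -0.79 and -0.70 with RPH1 and -0.61, -0.61 and -0.43 without it, which do not overlap. A two-sided exact permutation test of these medians gave p = 0.1, the smallest that 3 against 3 allows. The courses come from separate tables, and the sources used here do not say how values were scaled between them, so levels at 0 min (0.118 and 0.213) are not compared. The genotype of each library is taken from the labels, since H3K36me3 values at RPH1 in that course ran from 0.00272 to 0.378 and do not check the deletion.

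Across genes, the rate of gain hardly followed RNA level. Spearman's rho between slope and mean TPM was 0.0347 over 4816 genes in light, with an SD of 0.0821 when slopes came from single replicates. In dark it was -0.213 over 4813 genes (SD 0.0196), so genes with more RNA tended to have steeper loss. Given the 0 min level of the mark it was -0.0363, so a link with RNA level apart from the level of the mark is not shown. Changes in the mark and in RNA had rho -0.0133 over 4661 genes in light and 0.0130 over 4622 in dark. In light this turned to 0.279 in genes at or above the median level of the mark and to 0.115 with untransformed slopes, so no direction is given. These 4 relations are across genes, which are not independent replicates, and no p is given for them.

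The rph1Δ strain against WT asked which RNAs depend on the demethylase. GTT1 (YIR038C, IX 423809 to 424513), a glutathione transferase gene, rose from 23.3 ± 0.403 to 52.5 ± 2.04 TPM (log2 1.16 ± 0.06, adjusted p = 2.35e-09). Its neighbour HYR1 (YIR037W, IX 423128 to 423619), a peroxidase that senses hydrogen peroxide, rose from 136 ± 2.07 to 235 ± 4.95 TPM (0.78 ± 0.05, 1.03e-08). YGP1, a secreted glycoprotein made when nutrients run low, rose from 81.5 ± 3.94 to 158 ± 10.5 TPM (0.94 ± 0.04, 5.47e-10), and UGA2, which takes part in the use of 4-aminobutyrate, from 7.27 ± 0.652 to 15.5 ± 0.840 TPM (1.08 ± 0.07, 4.9e-08). Other rises were DBP1, an RNA helicase (1.03), YJL163C, of unknown function (1.00), GSP2, a Ran GTPase with a close paralog (0.91), and RRT8, a spore wall gene (0.90). Falls named by the same rule were IMD2, of GTP synthesis (-0.76 ± 0.08, 8.15e-06), COS8, of a subtelomeric family (-0.86), NFG1, a regulator of filamentous growth (-0.62), the transposon feature YLR410W-B (-0.58), the chaperone-like BTN2 (-0.52), ICL2, of propionate use (-0.50), and CRR1, a spore wall gene (-0.46). By edgeR 576 genes rose and 172 fell of 6088 tested. Only 11 changed by more than 1 log2 unit, and 725 of the 748 had no overlap between the libraries of the groups. Over all genes tested this share was 25.9%, against 10% by chance. Replicates of WT and of rph1Δ lay closer together than replicates of the courses. The chi-square per degree of freedom between pairs of replicates was 2.30 to 5.56 here and 10.9 to 74.8 in the courses. Depth differed as well, so the number of genes called in rph1Δ is not compared with the numbers in the courses. BTN2 was lost from the calls without 1 of the libraries and CRR1 without 3 of them.

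Genes described as repressed by Rph1, which serve autophagy and DNA repair, were higher in rph1Δ. ATG7 (YHR171W, VIII 445713 to 447605), the enzyme that activates the autophagy conjugation systems, rose from 3.70 ± 0.446 to 7.25 ± 0.302 TPM (0.95 ± 0.10, edgeR adjusted p = 5.77e-06), and ATG9, an autophagy membrane protein, by 0.66 ± 0.08 (4.48e-05). All 6 list members were higher and 4 passed, or 6 when adjusted over the list alone, where PHR1, the photolyase gene, joined at 0.27 (adjusted p = 0.181 over all genes). Camera called the list (adjusted p = 4.8e-06), but not with an estimated correlation (adjusted p = 0.15).

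Some respiration, a-cell and oxidative stress genes also rose, and some histone and sulfur genes fell. SDH1, of succinate dehydrogenase, rose from 13.6 ± 0.906 to 18.7 ± 0.770 TPM (0.45 ± 0.05, edgeR adjusted p = 2.16e-05), and LSC2, of the same cycle, by 0.36. Of 45 respiration genes 16 rose and 0 fell, or 17 and 0 adjusted over the list alone, and 37 were higher (adjusted p = 0.37 with an estimated correlation). AGA2 (YGL032C), the binding subunit of a-agglutinin, rose from 328 ± 19.3 to 512 ± 36.0 TPM (0.63 ± 0.08, 5.65e-05). With its anchor AGA1 (0.39) it was among 5 of 13 a-cell genes that rose, 7 adjusted over the list alone, all 13 being higher (0.19 estimated). For oxidative stress 9 rose and 1 fell of 33, the same numbers adjusted over the list alone, with ZWF1, which supplies NADPH, at 0.44 (0.35 estimated). The histone H4 gene HHF2 (-0.17) and H3 gene HHT2 (-0.18) were among 3 of 10 histone genes that fell, 6 adjusted over the list alone, all 10 being lower (0.58 estimated). SAM2, of S-adenosylmethionine synthesis, fell by 0.39 ± 0.04 and the methionine permease gene MUP1 by 0.43 ± 0.05. In that list 6 of 21 fell and 1 rose, the same numbers adjusted over the list alone (0.35 estimated). The G2/M list had CLB2, the mitotic cyclin (-0.18), and DSE2 (-0.14) among 2 of 16 that fell, 3 adjusted over the list alone (0.32 estimated).

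Remaining lists in rph1Δ held mixed or small changes. HXT4, a glucose transporter gene, rose by 0.77 ± 0.06 (edgeR adjusted p = 4.54e-07) while HXT7, nearly identical to HXT6, fell from 1.54 to 0.756 TPM (-1.06 ± 0.19, 0.00104), and the alternative carbon list had 2 rises and 1 fall, with a median of -0.02 and a mean of 0.02. The chaperone gene HSP82 rose by 0.36 and SSA1 by 0.31, with 5 rises and 1 fall in that list (5 and 2 adjusted over the list alone). Stress and reserve genes had 5 rises and 1 fall, TPS2, of trehalose synthesis, among them at 0.30. Amino acid genes had 4 rises, LYS20 (0.43) and ARG4 (0.32) included, and 5 falls (4 and 7 adjusted over the list alone). Iron genes had 5 rises, CCC2 (0.31) and TIS11 (0.37) included, and 0 falls (8 and 2). Ergosterol genes had 2 rises, ERG28 (0.38) included, and 3 falls, ERG2 (-0.26) included (2 and 5), and phosphate genes had 2 rises, PHO81 (0.25) included, and 1 fall, VTC4 at -0.18 (2 and 3). Of glycolysis genes only TDH1 passed (-0.37), of 137 ribosomal protein genes only RPS31 (-0.11; 0 adjusted over the list alone), although 114 were lower, and of ribosome biogenesis genes only RRP3 (-0.14; 0 adjusted over the list alone). In the H3K36 pathway list RPH1 alone passed. By edgeR 0 genes passed in the meiosis (17 measured, 13 lower), alpha cell (3 measured), G1/S, mitochondrially encoded and cryptic promoter lists. Camera called 9 of the 23 lists and 0 of them with an estimated correlation.

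**Figure D2:**
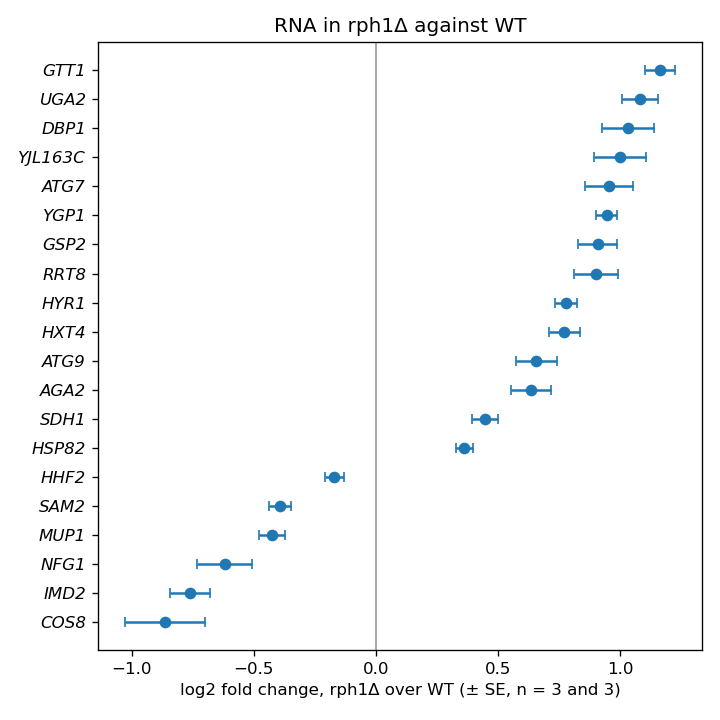
Log2 fold change of RNA in rph1Δ over WT (horizontal axis) for 20 named genes (vertical axis), with bars of ± SE from edgeR (n = 3 per group). GTT1 is at 1.16 and COS8 at -0.86.

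The dark to light RNA course asked which RNAs change as the mark is gained. At 40 min DDR2 (YOL052C-A, XV 231570 to 231755), a multistress response gene, rose from 906 ± 20.9 to 2380.3 ± 419.8 TPM (1.38 ± 0.22, limma adjusted p = 0.0173). SOL4, a pentose phosphate enzyme, rose from 15.6 ± 2.82 to 33.6 ± 5.86 TPM (1.06 ± 0.14, 0.0132), the ribosome-associated TMA10 by 1.00 ± 0.19, the chaperone HSP42 by 0.79 ± 0.12 and the peroxidase gene TSA2 by 0.68 ± 0.09. The named falls were INA1, of the plasma membrane (-0.56 ± 0.10), URA1 from 551 ± 19.7 to 409 ± 17.1 TPM (-0.43 ± 0.09, 0.0314), and NSR1, a nucleolar protein of ribosome assembly (-0.41 ± 0.10, 0.0491). GIS1, a paralog of RPH1, rose by 0.39 ± 0.06 (0.0173), and SWI4, a G1/S activator, by 0.27 ± 0.05. By limma on log2 TPM 209 genes rose and 15 fell of 5907, all 224 without overlap between groups, as were 35.7% of all genes. This count and its split depended on scaling and on single libraries. TPM moved the median gene by 0.10, and with median-ratio scaling 132 rose and 223 fell. With replicate number as a block 651 rose and 97 fell, and DESeq2 called 269 up and 418 down. Without 40 min replicates 1 or 3 the counts were 7 and 1, and without 0 min replicates 1, 2 or 3 they were 1, 2 and 569.

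As groups at 40 min, all 33 stress and reserve genes were higher, with a median of 0.68. Of them 17 rose, SOL4 and GND2 (0.70) among them, or 29 adjusted over the list alone (limma; adjusted p = 0.28 with an estimated correlation). Chaperone genes had 10 rises of 24, SSE2 at 0.62 included, or 20 adjusted over the list alone (0.28 estimated). Respiration genes had 11 of 45, CIT1 (0.50) and SDH2 (0.36) included, or 36 adjusted over the list alone, all 45 being higher (0.28 estimated), and oxidative stress genes had 6 of 32, PRX1 at 0.67 included, or 13 adjusted over the list alone (0.54 estimated). Ribosome biogenesis genes moved the other way, with 7 of 87 falling, UTP23 (-0.35) and ENP1 (-0.23) included, or 38 adjusted over the list alone, and 83 lower. Of 137 ribosomal protein genes 136 were lower, with a median of -0.18, and 1 fell, RPL9A (-0.32), or 0 adjusted over the list alone. These 2 lists were called with an estimated correlation too (adjusted p = 0.042 for each). In the iron list HMX1, heme oxygenase, rose by 0.53. Genes described as repressed by Rph1 had 0 calls, or 5 rises adjusted over the list alone (0.54 estimated).

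Changes at 20 and 60 min were fewer. At 20 min limma called 1 gene of 5907, YNL277W-A, which lies outside the naming rule and was picked after its values were seen, at 50.3 ± 1.84 against 20.6 ± 3.67 TPM (1.26 ± 0.12, adjusted p = 0.00707). At unadjusted p under 0.05 there were 532 genes, DESeq2 called 28 up and 62 down and edgeR 0, and limma called 0 without any one of the 20 min libraries and 2 without 0 min replicate 2. All 87 ribosome biogenesis genes were lower at 20 min, 0 called and 26 down adjusted over the list alone (adjusted p = 0.053 with an estimated correlation). Stress genes were higher in 32 of 33 and respiration genes in 45 of 45, with 0 calls either way. At 60 min (n = 2) limma called 3 rises and 0 falls: GCY1, a glycerol dehydrogenase gene, from 29.4 ± 0.948 to 54.1 ± 1.19 TPM (0.86 ± 0.06, adjusted p = 0.000559), TSA2 from 182 ± 4.72 to 319 ± 24.8 TPM (0.81 ± 0.11, 0.0352), and GND2, of the pentose phosphate pathway (0.78 ± 0.10, 0.0352). Median-ratio scaling gave 19 up and 67 down, replicate number as a block gave 281 up and 47 down, DESeq2 gave 121 up and 305 down, and the count was 83 without 60 min replicate 2 and 1 without 60 min replicate 1 or without 0 min replicate 1 or 3. DDR2 was at 2587 ± 824 TPM (1.48 ± 0.25) with an adjusted p of 0.0579. Of ribosomal protein genes 120 were lower at 60 min, with 0 calls, or 2 up and 87 down adjusted over the list alone (0.11 estimated), and 17 stress genes were up adjusted over the list alone (0.53 estimated).

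The light to dark RNA course asked which RNAs change as the mark is lost. At 90 min DAN1 (YJR150C, X 708811 to 709707), a cell wall mannoprotein gene made when oxygen is low, rose from 3.03 ± 0.686 to 32.0 ± 9.46 TPM (3.01 ± 0.24, limma adjusted p = 0.000144). Adjacent genes of biotin uptake and synthesis rose together: BIO3 (YNR058W, XIV 734291 to 735733) from 9.09 ± 1.87 to 60.7 ± 6.27 TPM (2.62 ± 0.18, 5.98e-05), BIO5 (YNR056C, XIV 731618 to 733303) from 3.04 ± 0.211 to 19.5 ± 2.07 TPM (2.34 ± 0.17, 7.84e-05), and BIO4 (YNR057C) by 1.82 ± 0.35 (0.0255). Further rises were YMR317W, of unknown function (2.44 ± 0.31), DAN4, related to DAN1 (1.67 ± 0.34), PBI1, of little-known function, from 146 ± 19.4 to 461 ± 27.3 TPM (1.66 ± 0.14), and TSA2 (1.54 ± 0.20). SAM1, a paralog of SAM2, fell from 255 ± 31.5 to 138 ± 16.1 TPM (-0.88 ± 0.12, 0.00404). So did RIB4, of riboflavin synthesis (-0.57 ± 0.06, 0.00123), the GTPase gene RAS1 (-0.61 ± 0.07, 0.00165), STR3, of methionine synthesis (-0.70), PHO3, an acid phosphatase (-0.69), IMD2 (-0.69), GPX2, a peroxidase (-0.63), and the S-methylmethionine permease MMP1 (-0.54). By limma 97 genes rose and 18 fell of 5884, 35 of them by more than 1 log2 unit, all without overlap between groups, as were 17.0% of all genes. With replicate number as a block 640 rose and 142 fell, DESeq2 called 248 up and 68 down, and edgeR 163 and 32. The count was 173, 39 and 38 without 90 min replicates 1, 2 and 3, and 66, 57 and 55 without 0 min replicates 1, 2 and 3, but DAN1, BIO3, BIO5, YMR317W, PBI1, TSA2, RAS1, RIB4 and ERG25 passed with any of the 6 libraries left out.

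Of 25 ergosterol genes 13 rose at 90 min, 3 at 60 min and 0 at 30 min. ERG25 (YGR060W, VII 610564 to 611493), a sterol methyl oxidase gene, went from 916 ± 26.5 to 1431 ± 56.4 TPM at 90 min (0.64 ± 0.06, limma adjusted p = 0.00066), and CYB5, its electron donor, from 346 ± 27.5 to 518 ± 16.5 TPM (0.59 ± 0.07). Adjusted over the list alone 20 rose at 90 min, with 24 higher and a median of 0.51 (adjusted p = 0.10 with an estimated correlation). Respiration genes had 9 rises of 45, ATP1 (0.39) and ATP2 (0.47) of the ATP synthase included, or 25 adjusted over the list alone, and this list was called with an estimated correlation too (0.040). Ribosomal protein genes were lower in this course too, as in light, with 8 of 137 higher at 90 min, a median of -0.16 and 0 calls (0.25 estimated). Histone genes were all 10 lower, with 0 calls over all genes, 4 falls adjusted over the list alone, a median of -0.20 and an estimated-correlation p of 0.020. Stress genes had 7 rises of 33, TKL2, a transketolase (1.48), and DDR2 (1.00) included, or 17 adjusted over the list alone, all 33 being higher (0.38 estimated). The methionine list had 4 falls of 21, MET6 (-0.47) included, or 5 adjusted over the list alone (0.25 estimated). Among chaperones HSP12 rose by 0.83 while SSA2 fell by 0.42, 2 others also fell, and the list median was 0.02, or -0.06 with median-ratio scaling, so its direction was not fixed (0.86 estimated). PRM1, of cell fusion, rose by 0.77, and the iron-sulfur scaffold gene ISU2 fell by 0.42. COX2 rose by 0.47 in a mitochondrially encoded list whose median was 0.31 and mean -0.09, with 1 call or 6 adjusted over the list alone (0.80 estimated).

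Earlier in the dark there were fewer calls. At 60 min DAN1 was at 19.4 ± 4.54 TPM (2.33 ± 0.24, limma adjusted p = 0.00485) and YHB1, a nitric oxide dioxygenase gene, rose from 83.9 ± 9.57 to 201 ± 16.4 TPM (1.26 ± 0.12, 0.00414). YMR317W rose by 1.80 ± 0.31, TKL2 by 0.93, DDR2 by 0.87, CYB5 by 0.47 and ERG25 by 0.45, and SSA2 fell by 0.40 and its fellow chaperone CPR6 by 0.34. In all 16 genes rose and 2 fell of 5884 (135 and 20 with replicate number as a block). DESeq2 called 91 up and 27 down, edgeR called 42 genes, median-ratio scaling gave 36 and leaving out the libraries numbered 1 gave 100, and the count was 5 without 60 min replicate 2 or 3, and 7 and 11 without 0 min replicates 2 and 3. Of ergosterol genes 3 rose at 60 min, or 18 adjusted over the list alone (0.10 estimated), of respiration genes 0, or 17 adjusted over the list alone (0.031 estimated), and all 10 histone genes were lower with 0 calls either way (0.026 estimated). At 30 min limma called 0 genes. There were 144 at unadjusted p under 0.05, DESeq2 called 12 up and 4 down, edgeR 0, and limma with replicate number as a block 6. Ergosterol genes were already higher in 24 of 25, 9 of them up adjusted over the list alone (0.083 estimated).

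**Figure D3:**
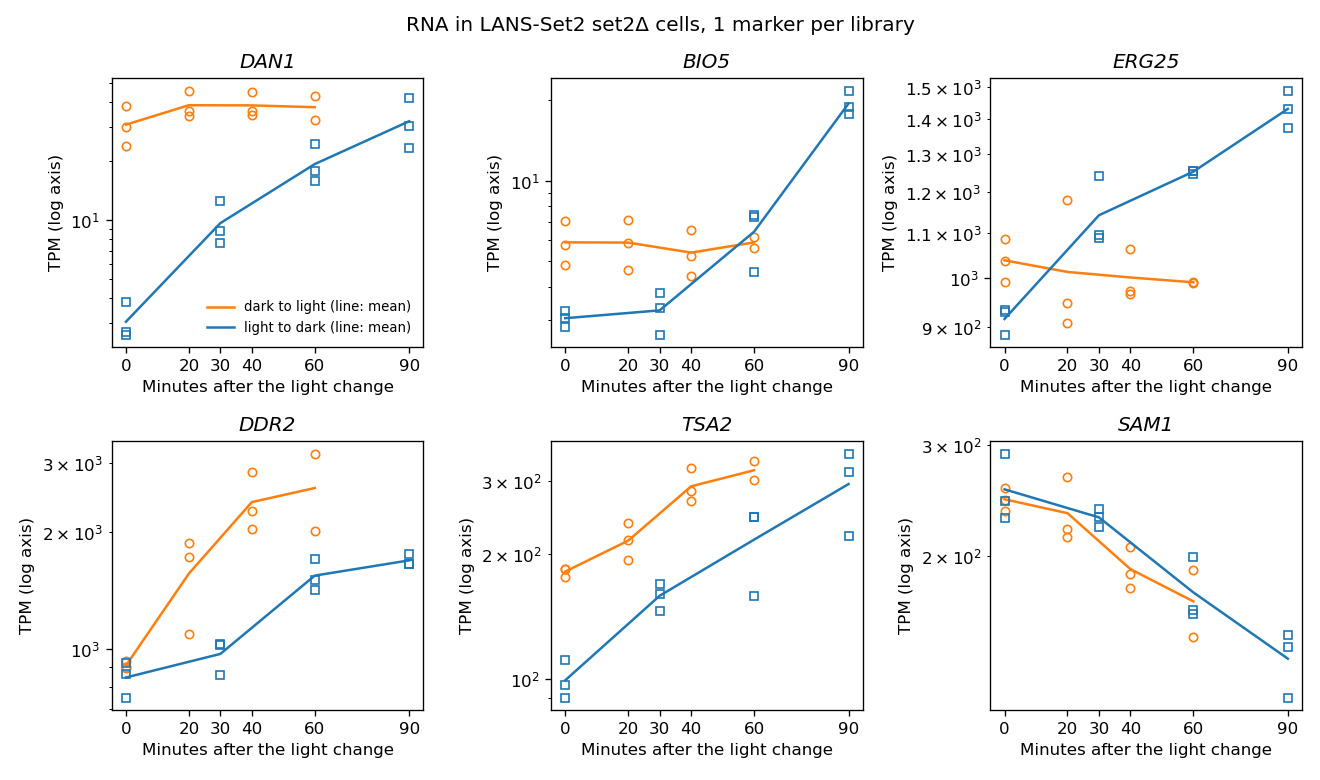
TPM (vertical log axis) against minutes after the switch (horizontal axis) for DAN1, BIO5, ERG25, DDR2, TSA2 and SAM1, with 1 marker per library and lines through means, orange circles for dark to light and blue squares for light to dark. DAN1 goes from 3.03 to 32.0 TPM in the light to dark course.

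Cells kept in light were set against cells kept in dark, by the 0 min libraries of the courses. DAN1 was at 3.03 ± 0.686 TPM in light and 30.7 ± 7.31 TPM in dark (-2.97 ± 0.20, limma adjusted p = 0.00948). Of amino acid synthesis genes lower in light, LYS20, the first enzyme of lysine synthesis, was at 79.6 ± 6.66 against 205 ± 28.1 TPM (-1.35 ± 0.12, 0.0173), and ARG1, of arginine synthesis, at 506 ± 59.1 against 1297 ± 159.3 TPM (-1.35 ± 0.12, 0.0173). Also lower were YNR064C, an epoxide hydrolase (-2.38 ± 0.16), YMR317W (-2.09), the transporter gene PUL3 (-2.04), DAN4 (-1.81), CSS1, a secreted protein (-1.75), ARO5 (-1.59), PAU23, of a large family of near copies (-1.52), and the drug exporter ATR1 (-1.26). Higher in light were the mitochondrial gene ATP6, at 240.0 ± 42.3 against 75.6 ± 25.8 TPM (1.70 ± 0.28, 0.0378), RGI1, of respiratory growth (1.09 ± 0.15), HXT7 (0.96), the cell wall gene CWP1 (0.88), YKR075C (0.68), PNS1 (0.62), IGD1, of glycogen control (0.57), and YFR052C-A, which has no R64 entry (1.123). By limma 24 genes were higher in light and 144 lower of 5870, all without overlap, as were 26.2% of all genes. DESeq2 called 136 higher and 323 lower, and edgeR 46 and 217. The count was 98 without dark to light 0 min replicate 1, 0 without replicate 2 or 3 there, and 9 and 3 without light to dark 0 min replicates 2 and 3, and light is confounded with course here.

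Of 45 amino acid genes 23 were lower in light, 40 adjusted over the list alone, with a median of -0.71 (limma; adjusted p = 0.40 with an estimated correlation). Sulfur genes had 7 of 22 lower, SUL2 (-0.89) and MET10 (-0.75) included, or 10 adjusted over the list alone (0.15 estimated), and iron genes 4 of 22, the mannoprotein FIT3 (-0.97) and FRE2 (-0.45) included, or 6 adjusted over the list alone (0.52 estimated). Ergosterol genes had 2 lower, ERG1 (-0.61) and ERG11 (-0.42), or 5 adjusted over the list alone (0.52 estimated), and TSA2 was lower too (-0.87). The cryptic promoter genes were all 5 lower in light, with a median of -0.21, 0 calls over all genes and 2 falls adjusted over the list alone, PCA1 (-0.72) and STE11 (-0.48), whose adjusted p over all genes were 0.119 and 0.183 (0.52 for the list, estimated). COX12 (-0.35) and RPS22B (-0.43) were the calls of the respiration and ribosomal protein lists.

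How far the RNA changes of the courses were alike across genes depended on the measure. Across 5856 genes the log2 change at dark to light 60 min and at light to dark 90 min had Pearson's r 0.104 and Spearman's rho 0.272. From single replicates r ran from -0.0773 to 0.166 (SD 0.0890 over 6 pairs of replicates), and r was 0.392 in genes with an average log2 CPM of at least 5, 0.272 in called genes and 0.222 for 40 against 60 min. The authors' lists of changed genes hold 88, 687 and 445 genes at 20, 40 and 60 min of light, and 14, 117 and 313 at 30, 60 and 90 min of dark. Every gene shared with the tests here had the opposite sign there, so those log2 values appear to be coded as 0 min over the later time. They are positive for 419 genes and negative for 268 at 40 min of light, 313 and 132 at 60 min, and 68 and 245 at 90 min of dark. On that coding falls outnumber rises at 40 and 60 min of light, unlike the calls here by TPM (209 up and 15 down at 40 min). At 90 min of dark rises outnumber falls, as they do here. Of the 224 genes called here at 40 min of light 181 are in the authors' list, and of the 115 called at 90 min of dark 98 are.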

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

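Tests chosen only after the result was seen are the direct comparison of the RNA courses, those of replicate 3 alone, of library scaling and of course means removed before relabelling for the slower loss of H3K36me3, those of light direction and of elapsed time for the stress genes, and those for the DAN1 and ergosterol genes. The comparisons, the gene lists and the tests of a constant background, of TPM composition and of other groupings of the samples were set before the data were examined.

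Some biotin and anaerobic cell wall genes rose in the dark and were not called in the light, and this difference between courses was tested directly. The times compared differ, 90 min of dark against 60 min of light, so direction and elapsed time are not separated. In dark BIO5 was at 4.54 to 7.43 TPM at 60 min and 17.8 to 21.8 TPM at 90 min, so most of its rise came after 60 min. DAN1 in dark was already at 15.8 to 24.5 TPM at 60 min, from 2.60 to 3.82 TPM at 0 min. The change at light to dark 90 min minus that at dark to light 60 min (n = 2) was 2.41 for BIO3 (limma adjusted p = 8.2e-05), 2.33 for BIO5 (0.000208), 2.71 for DAN1 (0.000648), 2.45 for YMR317W (0.00732) and 1.57 for PBI1 (0.00653). It did not pass for BIO4 (1.68, 0.113) or DAN4 (1.56, 0.220), of the same groups as BIO3 and DAN1. DAN1 changed by 3.01 in dark and 0.30 in light, BIO3 by 2.62 and 0.21, and BIO5 by 2.34 and 0.01. ERG25 differed by 0.71 (0.00727), and GPX2 and ISU2 differed by -1.24 (0.00653) and -0.53 (0.0410), GPX2 being at -0.63 in dark and 0.61 in light. In all 26 of 5900 genes differed, 19 of them higher in dark, and 539 had an unadjusted p under 0.05. They include 8 of the 36 named genes tested.

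DAN1 and 13 of 25 ergosterol genes rose by 90 min of dark, DAN1 and 2 of the 25 were called lower in constant light, and both comparisons share the light to dark 0 min libraries. In what follows each SE over libraries belongs to the list mean given with it, not to the median. Low values in those 3 libraries alone would leave later times level, but the ergosterol median at 90 min over 30 min was 0.28 (mean 0.27, SE 0.11 over libraries), with 24 of 25 genes higher, and 0.23 (mean 0.21, SE 0.0321) with median-ratio scaling. This argues against it, narrowly by TPM and more clearly by the other scaling. A response to light in either direction would lower DAN1 and the ergosterol genes in light. DAN1 was instead 0.30 higher at dark to light 60 min, though not called. The ergosterol median there was -0.0420 (mean -0.0508, SE 0.0419), or -0.12 (mean -0.13, SE 0.0462) with median-ratio scaling, where 3 of 25 were higher. The ergosterol fall exceeds 2 SE only with the latter, so for that list the outcome depends on scaling and cannot be told apart with 2 libraries. Shared libraries by themselves gave a correlation of -0.501 between these comparisons in simulation, against -0.419 observed over 5844 genes, and a covariance of -0.0276 against -0.0380 observed. These point opposite ways and no spread was computed, so the mirror image across genes is left open. A biological response to darkness or to loss of the mark remains open and untested, since no course without LANS-Set2 is used here.

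General stress genes were higher in both RNA courses, with 17 of 33 called at dark to light 40 min and 7 at light to dark 90 min, although light moved in opposite directions. TPM composition as the whole cause is argued against: after median-ratio scaling the list median was still 0.58 (mean 0.58, SE of the mean 0.14) at dark to light 40 min and 0.38 (mean 0.51, SE of the mean 0.10) at light to dark 90 min. A response that follows light or the mark in 1 direction would by itself give opposite signs, but the median was 0.46 at light to dark 90 min with 33 of 33 genes higher. This restates the values that showed the pattern and is no separate test. A directional part under another cause is not excluded. Elapsed time or handling cannot be told apart, as no unswitched culture was sampled: the median was above 0 at 6 of 6 later time points by TPM, though at light to dark 30 min it was 0.01, or -0.01 with median-ratio scaling. These values are consistent with a response to elapsed time or handling, as a hypothesis.

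Loss of H3K36me3 was slower in the set2Δ rph1Δ course, by a median of 0.20 per hour. Limma's interaction, fitted without a term for replicate number, called 0 genes (119 of 4712 at unadjusted p under 0.05, all of them positive). A constant background added to every gene would slow weakly marked genes most, but the difference was 0.0706 larger in the highest 20% of genes by level than in the lowest 20% (SE 0.0528, n = 3). This meets the bound of 1 SE set for it but argues against it only narrowly, as highest minus lowest ran over replicates from -0.189 to -0.108 with RPH1 and from -0.139 to 0.00042 without it. Replicate 3 is not the whole cause, since the mean median slope of replicates 1 and 2 was -0.609, above the set2Δ replicates. Library scaling that differs between courses cannot be told apart, because centring each library, which gave -0.0210, removes any change common to all genes. Among 100 groupings of the libraries across these courses 72 gave a difference as large as the real 0.20, the highest other being 1.137 with 4595 genes called. These groupings mix libraries of separate tables, whose scaling is not stated and whose 0 min medians were 0.118 and 0.213. Level differences between the tables thus enter as slopes. With course gene means removed 26 of 100 were as large, the highest other being 0.51, but libraries of 1 replicate were still split up. Neither count can decide about chance. The two-sided exact permutation test of replicate median slopes gave p = 0.1, the smallest that 3 against 3 allows, so chance is not excluded. The loss of a demethylase remains a candidate explanation that these values neither exclude nor single out.

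Other groupings of the samples were counted for comparisons with at least 3 samples per group, which leaves out 60 min of light in RNA. With 3 samples against 3 there are 10, too few for a share under 0.05. Real and highest other counts were 748 and 0 for rph1Δ (1 of 10 as large), 1 and 1 at 20 min of light (3 of 10), 224 and 1 at 40 min (1 of 10), 0 and 1 at 30 min of dark (10 of 10), 18 and 1 at 60 min (1 of 10), 115 and 0 at 90 min (1 of 10), and 168 and 2 for light against dark (1 of 10). For H3K36me3 at the last time point they were 4813 and 5, 4789 and 9, and 4598 and 34 (1 of 10 each). For slopes, with 100 groupings, the real order of time gave the highest count in light (4810, highest other 4696, 1 as large) and in dark (4793, 4581, 1 as large). Shuffled orders came close to these counts, so the count sets the real order apart only narrowly. Library medians over time gave a permutation p of 4e-05 in light and 3e-05 in dark. In set2Δ rph1Δ (4689, 4796) 3 groupings were as large by the slope count, but other groupings exceeded the real count. The slope test there called only 3 genes without replicate 2. Because this count can be as high under other orders of time, chance is not called excluded for that course.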

How the results depend on the processing

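Tests chosen only after the result was seen are the pseudocounts of 0.1 and 5, edgeR on recovered reads and leaving out all libraries numbered 1; the other alternatives were chosen earlier. Of 2781 values of named genes under alternatives 2184 had the direction and side of the threshold first reported, 500 had the direction but missed the threshold (377 of them with a library left out), 30 now passed it, 39 had no call and moved, and 28 reversed. In rph1Δ 460 of 500 values had both. The cause was not tested for any change below unless one is named.

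Simulated 2-fold RNA changes were called in at least 85.1% of genes, but 1.5-fold changes in 64.2% and 60.6% at 30 and 60 min of dark and 55.2% in light against dark. Simulated genes and libraries varied independently, so larger real changes can be missed too. At 60 min of light 0 called genes changed by more than 1 log2 unit, while DDR2 at 1.48 was not called. Depth and replicate spread were not separated in the simulation. ChIP depth is unknown. The 3 planned H3K36me3 comparisons (WT against set2Δ, and LANS-Set2 at 0 min against WT in light and against set2Δ in dark) were not run, because their samples are not analysed here.

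The tool changed the counts of the courses. DESeq2 on recovered reads called 90, 687 and 426 genes at 20, 40 and 60 min of light (28 up and 62 down, 269 and 418, 121 and 305), 16, 118 and 316 at 30, 60 and 90 min of dark (91 up and 27 down at 60 min), and 459 in light against dark (136 up and 323 down, against 24 and 144 first reported). EdgeR on recovered reads called 0, 482 and 139 in light (600 at unadjusted p under 0.05 at 20 min; 202 up and 280 down at 40 min; 39 up and 100 down at 60 min), 42 and 195 at 60 and 90 min of dark and 263 in light against dark. At 30 min of dark it called 0 (166 at unadjusted p under 0.05), as did limma (144). Median-ratio scaling of TPM called 355 and 86 genes at 40 and 60 min of light (19 up and 67 down at 60 min, against 3 and 0 by TPM) and 36 at 60 min of dark. It called 132 up and 223 down at 40 min, against 209 and 15 by TPM, as it moved the median gene by -0.09, and 181, 144 and 174 of the 224 genes first called were shared with DESeq2, median-ratio scaling and edgeR. Fits of the compared time points alone, which have fewer samples, called 0, 74, 0, 1, 2 and 29. Without the libraries numbered 1 the counts were 0 and 0 at 40 and 60 min of light and 2, 100 and 415 in dark, with 2 samples or 1 left per group. In rph1Δ counts stayed within 1.5 times 748 under every alternative (DESeq2 528, of which 524 shared).

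Replicate numbers as a block gave 748 and 328 genes at 40 and 60 min of light, 6, 155 and 782 in dark, 702 in rph1Δ and 1 at 20 min of light. For H3K36me3 the block gave 4810, 4796 and 4744 slopes and 4811, 4793 and 4758 genes at the last time point. The slope interaction between the dark courses was not refitted with it. Residuals of libraries with 1 number correlated above 0.1 in 0 of 3 pairs for WT and rph1Δ, 11 of 15 and 14 of 18 for the RNA courses and 15, 10 and 13 of 18 for H3K36me3. Among libraries of other groups the best match had the same number for 9 of 11 and 9 of 12 libraries of the RNA courses. For H3K36me3 this held for 12, 7 and 10 of 12, and for WT and rph1Δ for 1 of 6. In the courses the numbers thus tie most libraries together, but not all. As the labels do not state shared cultures, the fits first reported leave the numbers out. If they do mark shared cultures, the RNA counts first reported at 40 and 60 min of light and in dark are too low. The count at 20 min of light stays the same, and H3K36me3 counts change little.

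Leaving out 1 library gave 526 to 698 genes in rph1Δ, 0 to 2, 1 to 569 and 1 to 83 at 20, 40 and 60 min of light, 0, 5 to 19 and 38 to 173 at 30, 60 and 90 min of dark, and 0 to 115 in light against dark. The lone sample left at 60 min of light is assumed to vary like the others. At 40 min of light the counts were 7, 154 and 1 without 40 min replicates 1, 2 and 3, and 1, 2 and 569 without 0 min replicates 1, 2 and 3. At 60 min of light they were 1 and 83 without 60 min replicates 1 and 2, and 1 without 0 min replicates 1 or 3. At 20 min the count was 0 whichever 20 min library was left out and 2 without 0 min replicate 2. At 60 min of dark it was 5 without 60 min replicates 2 or 3, and 7 and 11 without 0 min replicates 2 and 3. At 90 min it was 173, 39 and 38 without 90 min replicates 1, 2 and 3, and 66, 57 and 55 without 0 min replicates 1, 2 and 3. In light against dark it was 98, 0 and 0 without dark to light replicates 1, 2 and 3, and 9 and 3 without light to dark replicates 2 and 3.

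H3K36me3 slope counts with 1 replicate left out were 4807 to 4815 in light, 4768 to 4808 in dark and 3 (without replicate 2) to 4718 in set2Δ rph1Δ, where the median slope was -0.52 to -0.62. Counts at the last time point were 4813 to 4816, 4743 to 4804 and 0 (without replicate 2; 12 without replicate 1) to 4755, the median change in set2Δ rph1Δ being -0.80 to -0.97, so calls were lost with little change in size. Library median correlations were 0.927 to 0.976, -0.976 to -0.927, and -0.927 to -0.634, where the permutation p was 0.0548 without replicate 1 and 0.109 without replicate 2. The interaction called 0 to 26 genes (26 without replicate 1, 3 without replicate 2) and 1 with no filter, and the median difference was 0.16 to 0.22.

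Centring each library on its median removes by construction the change common to all genes. Slope counts were then 2460 in light (676 up, 1784 down), 944 in dark (672 up) and 67 in set2Δ rph1Δ, last time point counts 2349, 651 and 37, and the interaction called 4 with a median difference of -0.0210. All 28 reversals came from it. In light URA1 was then at -0.82, RPL41A at -0.83, RPS28B at -0.93, YAR009C at -0.98, YER138W-A at -1.002, YLL066W-B at -1.20, AVO1 at -0.0771 and RRP36 at -0.26. In dark PMP2 was at 0.32, MIN10 at 0.34, RPL41A at 0.37, YLR466C-B at 0.37, YCR006C at 0.38, YLR112W at 0.42, PCA1 at 0.0516, FLO8 at 0.0681, STE11 at 0.0871, AVO1 at 0.0462 and GAL80 at 0.11. In set2Δ rph1Δ WSC4 was at 0.17, YDR274C at 0.18, RPS28B at 0.18, YLR256W-A at 0.19, YOR024W at 0.20, YJL156W-A at 0.22, FLO8 at 0.0348, STE11 at 0.0480 and AVO1 at 0.0105. Pseudocounts of 1/100 of the table median and of the median left the slope and last time point counts within 1.5 times those first reported, but not the sizes. With the pseudocount at the median, median slopes went from 1.87 to 1.09 in light, from -0.75 to -0.46 in dark and from -0.55 to -0.31 in set2Δ rph1Δ, and the 60 min change in light from 1.85 to 1.06. The median log2 changes at 90 min of dark, -1.12 in set2Δ and -0.86 in set2Δ rph1Δ, shrank by 0.43 and 0.38. With 1/100 of the median the sizes grew instead. Median changes at the last time point moved by 0.17 in light, -0.08 in dark and -0.07 in set2Δ rph1Δ.

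Across genes, the light slope and RNA level had rho -0.132 with slopes of untransformed values, -0.0660 in genes above the median level, -0.0945 given the 0 min mark, 0.119 given gene length and 0.125 from replicate 1 alone, so no direction is claimed. In dark these were -0.125, -0.245, -0.0363 and -0.257, with Pearson's r -0.189, and -0.181 and -0.167 from replicates 2 and 3 alone. Mark change against RNA change had 0.115 untransformed and 0.279 in highly marked genes in light, and -0.0425 untransformed in dark. The RNA courses correlated at 0.272 by Spearman's rho, 0.272 in called genes, 0.222 for 40 against 60 min and 0.392 in genes with log2 CPM of at least 5.

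List calls depended on the test. With an estimated correlation 0 lists were called in rph1Δ, at 20 and 60 min of light, at 30 min of dark, in light against dark and in the H3K36me3 fits, and 2 each at 40 min of light and at 60 and 90 min of dark, against 9, 8, 12, 7, 11 and 4, 8, 7 and 1, and 10, 9 and 10 with the preset one. Fry called 8, 1, 6 and 1 (rph1Δ and light), 0, 3 and 4 (dark), 2 (light against dark), 21, 21 and 21 (slopes) and 0 (interaction).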

Other observations

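Tests chosen only after the result was seen are the comparison of residual spread at RPH1 and the look at its neighbour; the other values below carry no test.

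Gain and loss of the mark were also set against the RNA level of each gene. When genes were divided by mean TPM into 5 equal groups from low to high, median slopes in light were 1.77, 1.92, 1.91, 1.88 and 1.82 per hour, and in dark -0.70, -0.75, -0.76, -0.77 and -0.77. The median 0 min mark in the light to dark course was 0.0772 in the lowest group and 0.172 in the highest. RPL41A, a short ribosomal protein gene, was shallow in gain and in loss, and RPS9A, another ribosomal protein gene, was steep in both (2.31 and -1.12 per hour).

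RPH1 itself had uneven H3K36me3 values in the set2Δ rph1Δ course, from 0.00272 to 0.378 between libraries. Its residual SD was 1.29, above 99.9% of genes, against 0.230 and 0.127 in the courses with RPH1 intact. It was near 0 in 2 of 12 libraries, replicates 1 and 2 at 60 min (0.00272 and 0.00313), and at least 0.0338 in the other 10. The values therefore do not check the deletion by a signal of 0, and the genotype of each library of that course is taken from the labels. How the signal is formed over a deleted gene is not stated.

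LEU2 was at 253 ± 21.2 TPM in the LANS-Set2 cells at dark to light 0 min and 0.238 ± 0.0737 TPM in WT. ADK2, the neighbour of RPH1, was higher by 0.45 in rph1Δ (edgeR adjusted p = 0.0172).

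The authors' models were set beside the slopes here. Bounds of the ZOIBeta estimate lay above 0 for 5142 of 5347 genes and below 0 for 0 in light, and below 0 for 4231 and 4232 genes and above 0 for 0 in the set2Δ and set2Δ rph1Δ dark courses. Bounds of the ZINeg estimate lay above 0 for 4649 genes in light, and below 0 for 3357 and 195 genes in those dark courses. Spearman's rho across genes with the slopes here was 0.826, 0.742 and 0.492 for ZOIBeta and 0.944, 0.875 and 0.782 for ZINeg. The mean normalized counts of the authors' RNA tables were 1.03 times those from recovered reads, which is unexplained.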
